A study of Mus musculus with 5 samples.

How the data were processed

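Single-cell RNA was profiled from mouse oesophagus and tongue in 5 libraries made with the 10x Genomics Chromium 3' v3 kit and sequenced on an Illumina NovaSeq, with 1 library in each of 5 groups. Per the labels, the groups are all living cells of the thoracic oesophagus of wild type CD1 mice, all living cells of the cervical (upper) oesophagus of wild type CD1 mice, EpCAM-sorted cells of the cervical oesophagus of wild type CD1 mice, EpCAM-sorted cells of the cervical oesophagus of Krt8-YFP mice, and EpCAM-sorted cells of the circumvallate and foliate papillae of the tongue of Krt8-YFP mice. EpCAM is a surface protein of epithelial cells, and Krt8 is a keratin of simple epithelia and taste buds. They are called here the thoracic library, the ungated cervical library, the sorted wild type cervical library, the sorted Krt8-YFP cervical library and the tongue library. No paired analysis was possible because the titles pair the sorted Krt8-YFP cervical library with the tongue library but each group holds 1 library.

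The deposited matrices hold a UMI count per gene and cell barcode, checked as whole numbers, for barcodes called as cells by the authors. Per the submitters' processing notes, reads were handled with bcl2fastq, Cell Ranger 3.1.0 and STAR on the mouse build mm10. The feature lists differ between libraries. The ungated and the sorted wild type cervical libraries list 31053 features, the thoracic library lists 31057, which adds 4 reporter sequences, and the sorted Krt8-YFP cervical and tongue libraries list 32286 from a newer annotation. Joint work used the 30406 gene identifiers that all 5 libraries share. The older list holds 647 identifiers of its own and the newer list 1880, and 597 shared identifiers have another symbol in the newer list. All wild type libraries carry the older list and both Krt8-YFP libraries the newer one, so genotype and annotation are confounded. Positions of genes are from the GRCm38 annotation.

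Cells were kept with at least 500 genes, at least 1000 UMIs and at most 15% mitochondrial UMIs. Scrublet, as implemented in scanpy 1.11.5, was run per library with an expected doublet share of 0.8% per 1000 barcodes. It removed 352 cells of the thoracic library, 56 of the ungated cervical, 1 of the sorted wild type cervical, 0 of the sorted Krt8-YFP cervical and 5 of the tongue library. In the 3 sorted libraries it marked under 0.5% of cells and is taken not to have worked there, so an alternative removes the expected share with the highest doublet scores. The cells kept number 29543. Counts were scaled to the same total per cell and log-transformed. The 3000 most variable genes gave 30 principal components, 15 nearest neighbours per cell and a shared-neighbour graph, which was clustered by the Leiden method at resolution 1 with igraph 0.11.9, without batch integration. Genes of the readout lists, mitochondrial genes and ribosomal protein genes were left out of clustering.

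Each of the 33 clusters was named from 28 marker lists fixed beforehand, by the mean log2 level of a list over its mean across clusters. The score that gave a name was 4 for classes outside the epithelium and for gland, 3 for taste buds and taste cell types and 2.5 for proliferating cells. Taste buds were scored by a core of their list, Krt8, Krt18, Kcnq1 and Krt20, which was not itself 1 of the lists fixed beforehand. Cluster 21 scored 3.22 by the whole taste bud list but 1.98 by this core, so it stayed outside the taste-bud-like class. A basal or suprabasal cluster needed no rival list more than 0.5 above its own. These scores were set after the clusters were seen. Class names stand for cells like that type by these markers. Clusters that met none of the naming rules stayed unnamed, and an unnamed cluster counted as epithelial with at least 100 CPM of Epcam. The taste-bud-like cells were clustered again into 11 sub-clusters, named type II-like or type III-like from their markers. Type I-like cells, the support cells of taste buds, could not be named in this way. Suprabasal cluster 9, led by Cyp2a5, Slc5a8 and Aldh1a3, failed the check of its top 10 genes, which held 0 suprabasal markers and 1 gland marker, Aqp5. It holds 74.9% of the suprabasal cells of the sorted wild type cervical library. Suprabasal cells are therefore compared only by cluster number.

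Values per class are sums of raw counts over its cells in a library, given as CPM, the UMIs of a gene over all UMIs of the class on the usual scale, with exact Poisson intervals, and shares of cells with exact Clopper-Pearson intervals, all at 95%. The intervals cover counting error only. There are no replicates, so no difference was tested and no p-value is given. Against a count of 0 a fold uses a floor of 3 counts per library and is written as a lower bound. Ratios on the log2 scale have 10 CPM added. A gene was counted in a comparison when its ratio was at least 2-fold, with at least 50 CPM in 1 of the libraries and UMIs in at least 10% of the class cells where it was higher, in classes of at least 20 cells per library. For cervical against thoracic basal cells the ratio had to hold in both wild type cervical libraries. The named genes of a comparison are the 10 highest and the 10 lowest log2 ratios among those genes, leaving out mitochondrial, ribosomal protein, haemoglobin, immunoglobulin and sex-linked genes and unnamed gene models. Members of the fixed lists may be named in addition. Not every gene that this rule names is reported here.

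For the 22 readout lists, the median log2 ratio of members with at least 10 CPM in 1 of the libraries was compared with 10000 random lists of the same size drawn from 20 bins of expression, and called outside when it lay beyond their central 95%. Lists with under 4 such members got no median. The random lists describe genes within the same pair of libraries and are not replicates. To compare shares of cells across depths, each cell was thinned to 2000 UMIs, and a proliferating cell needed UMIs of at least 2 of 8 proliferation markers. The marker lists, readout lists, filters, named-gene rule and most alternatives were chosen before the data were examined. The alternatives tried were looser and stricter cell filters, doublet calls kept, other resolutions and seed, clustering of each library alone, readout genes kept in clustering, edgeR 4.0.16 TMM factors in R 4.3.3, a mean over cells, totals without mitochondrial and ribosomal protein genes, 1 CPM added, no CPM minimum, and cells thinned to equal UMIs and equal cell numbers. Further alternatives named in the closing section were added after the data were seen.

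The gene comparison was tested on simulated data drawn as Poisson counts from the pooled class sums at the real class totals, with known folds for some genes. Of 50 genes changed 2.5-fold in each comparison, between 88% and 100% were called, all in the right direction, 4-fold and 8-fold changes were all called, and no unchanged gene was called. The draws hold counting error only, around 1 profile for all libraries. They therefore cannot show how many unchanged genes would be called between real libraries, where animals and preparation differ. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9 were used.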

Results

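The data are UMI counts of single cells in 5 libraries, 1 per group, so no value below has a replicate. The deposited barcodes number 10672 in the thoracic library, 9102 in the ungated cervical, 5164 in the sorted wild type cervical, 6767 in the sorted Krt8-YFP cervical and 5952 in the tongue library. Total UMIs were 162824441, 53877136, 74292490, 97120224 and 84576207, in that order. The cells kept number 8711, 5144, 4126, 6204 and 5358, with medians of 11964, 5566.5, 12469, 13754 and 13611.5 UMIs per cell. The ungated cervical library was the shallowest, and 38.0% of its barcodes exceeded the limit on mitochondrial UMIs, against 10.0% in the thoracic library. Genotype goes with the feature list used for counting. The thoracic library held 0 UMIs of the Y-linked gene Ddx3y, both wild type cervical libraries held Ddx3y and the X-inactivation RNA Xist, and the Krt8-YFP libraries held 6 and 12 UMIs of Xist, so sex of the animals also differs between groups.

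The first question was whether the oesophagus holds cells like those of taste buds, and how their share compares with the tongue. Taste-bud-like cells, with the simple-epithelium keratin Krt18 and the taste bud potassium channel gene Kcnq1, were found in all 3 cervical libraries and in the tongue library, and none was found in the thoracic library. They made up 0 of 3789 epithelial cells in the thoracic library, which allows a share of up to 0.0792%. They made up 1.17% (95% interval 0.851 to 1.58) in the ungated cervical, 10.5% (9.56 to 11.5) in the sorted wild type cervical, 11.9% (11.1 to 12.8) in the sorted Krt8-YFP cervical and 7.55% (6.85 to 8.31) in the tongue library. The EpCAM sort can set these shares, so only the thoracic and the ungated cervical library, sorted alike, bear on the segments. Krt18, on chromosome 15 from 102028180 to 102032027, stood at 2930 CPM (2726 to 3145) in taste-bud-like cells of the ungated cervical library, 2800 in the sorted wild type cervical, 2762 in the sorted Krt8-YFP cervical and 3029 in the tongue library, against 5.05 CPM in thoracic basal cells. Kcnq1 stood at 84.4, 51.7, 49.7 and 42.2 CPM in those taste-bud-like cells and at 0.0488 CPM in thoracic basal cells.

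Taste-bud-like cells were also counted by at least 3 taste markers per cell after thinning to 2000 UMIs. These shares were 0.0265% in the thoracic, 1.25% in the ungated cervical, 9.53% in the sorted wild type cervical, 12.5% in the sorted Krt8-YFP cervical and 10.5% in the tongue library, and 5.01%, 5.46%, 35.8%, 31.2% and 26.2% without thinning. Fibroblasts met the same count after thinning in 1.94%, 3.24%, 6.90%, 2.62% and 3.90% of cells. The counted markers include the type I taste list, which scored 1.84, 1.41, 1.66 and 1.97 in the fibroblast clusters 1, 5, 16 and 19. Fibroblasts are therefore not a clean background, and the thoracic and the ungated cervical shares do not exceed theirs. After thinning the intervals of these shares, 0.000671% to 0.148% and 0.909% to 1.69%, were apart. Without thinning their intervals, 4.34% to 5.76% and 4.75% to 6.25%, overlap. Clusters were named by Krt8, Krt18, Kcnq1 and Krt20 or by the type II and type III lists, and all these genes are also counted markers. The measures are therefore not independent. Krt8 was low in all libraries with the older feature list, so wild type and Krt8-YFP libraries were not counted alike.

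**Figure D1:**
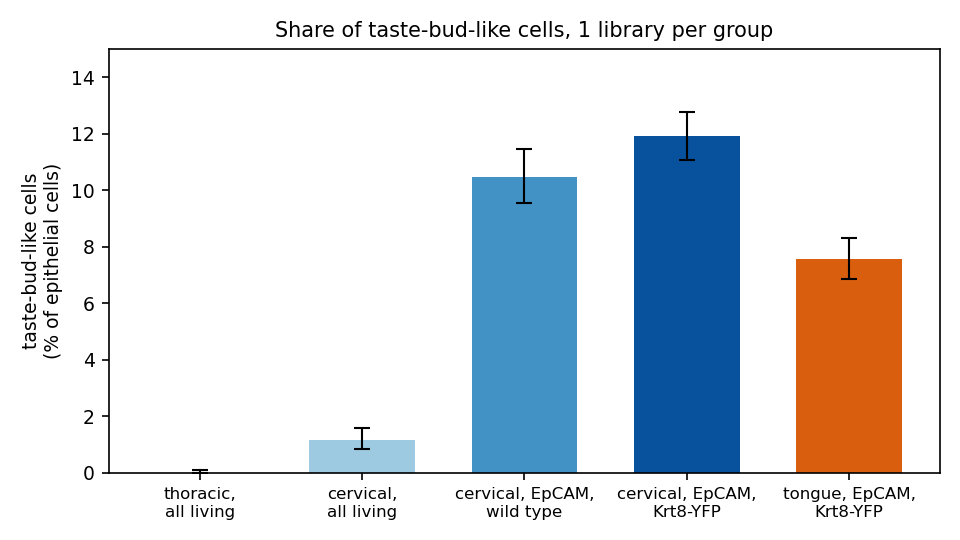
Share of taste-bud-like cells among epithelial cells (percent, vertical axis) in each of the 5 libraries, with exact Clopper-Pearson 95% intervals as error bars that cover counting error only. The 3 EpCAM-sorted libraries sit between 7.55% and 11.9%, and the thoracic library is at 0.

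The next question was which taste cell types the cervical cells resemble. Both type II-like cells, the receptor cells for sweet, umami and bitter, and type III-like cells, the sour-sensing cells with synapses, were found in both sorted cervical libraries and the tongue. Type II-like cells made up 10.0% (7.37 to 13.3) of taste-bud-like cells in the sorted wild type cervical, 10.1% (7.96 to 12.6) in the sorted Krt8-YFP cervical and 8.16% (5.65 to 11.3) in the tongue library. Type III-like cells made up 8.41% (5.96 to 11.5), 14.3% (11.8 to 17.2) and 18.9% (15.1 to 23.1). The ungated cervical library held 0 type II-like cells among 43 taste-bud-like cells, which allows a share of up to 6.98%, and 2 type III-like cells. With each library clustered on its own the type II-like share of the sorted wild type cervical library was 16.3%, and with doublet calls kept it was 15.3%, against 14.5% in the tongue. By at least 3 markers per cell after thinning, type II-like shares were 8.48%, 10.951% and 9.50% and type III-like shares 7.73%, 13.4% and 15.3% in the 3 sorted libraries.

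In type II-like cells, Gnat3, the taste G protein alpha subunit gustducin on chromosome 5 from 17962549 to 18019834, stood at 2230 CPM (2053 to 2417) in the sorted wild type cervical, 4487 (4321 to 4658) in the sorted Krt8-YFP cervical and 3145 (2972 to 3326) in the tongue library. Trpm5, the cation channel of taste transduction, stood at 432, 568 and 501 CPM, and the phospholipase gene Plcb2 at 751, 1085 and 918 CPM. The sweet and umami co-receptor gene Tas1r3 stood at 30.3 (13.1 to 59.8), 55.3 (38.3 to 77.3) and 94.6 (66.6 to 130.4) CPM. The summed taste receptors reached 724 (625 to 834), 571 (513 to 634) and 713 (632 to 802) CPM in type II-like cells, against 1.08, 0.227 and 0.717 CPM in basal cells. In type III-like cells the synaptic gene Snap25 stood at 641, 588 and 568 CPM in the same 3 libraries. Car4, the carbonic anhydrase of sour-sensing cells, stood at 955, 1210 and 197 CPM, and the secretory granule gene Chga at 1392, 1299 and 268 CPM, so both were lower in the tongue. Different sub-clusters hold these cells, since 60 of the 74 type III-like cells of the tongue lie in a sub-cluster led by Pkd1l3 that has no cervical cell. Gnat3, Trpm5, Plcb2, Snap25, Car4 and Chga are markers by which these types were named. Their presence in the named cells is therefore no separate evidence of the type. The taste receptors, Tas1r3 among them, were used neither for clustering nor for naming.

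Within each library, taste-bud-like cells were compared with basal cells by the fixed lists. By median, 3 lists were higher in taste-bud-like cells and 3 lower, in both sorted cervical libraries and in the tongue. Synapse and transmitter genes had median log2 ratios of 1.598 in the sorted wild type cervical, 1.523 in the sorted Krt8-YFP cervical and 1.495 in the tongue library, with 7 of 9, 10 of 11 and 8 of 11 members at least 2-fold higher. Gad2, an enzyme of GABA synthesis, was 3.84, 4.04 and 3.41 higher on the log2 scale. Taste transcription factors had medians of 0.94, 1.56 and 1.77, with 6 of 13, 10 of 14 and 12 of 15 higher. Hes6, a regulator of neural differentiation, was 4.07, 4.20 and 3.89 higher, Prox1 2.66, 3.42 and 3.75, and Pou2f3, required for type II cells, 1.60, 2.21 and 2.18. Tuft cell genes had medians of 1.16, 1.12 and 1.43, with the cytoskeletal gene Avil 4.65, 4.71 and 4.79 higher. The FGF and EGF pathway had medians of -0.30, -0.56 and -1.07 with 5 of 14, 5 of 14 and 8 of 15 members at least 2-fold lower and 2, 2 and 1 higher, cell adhesion and matrix genes -0.57, -0.71 and -0.86 with Col17a1, a hemidesmosome collagen, at -1.53, -1.69 and -2.58, and innate defence genes -1.22, -0.28 and -1.53. Of cell adhesion and matrix genes 4 of 18, 5 of 19 and 7 of 19 were lower and 1 higher in each library, and of innate defence genes 6 of 12, 3 of 10 and 8 of 12 were lower and 2, 2 and 1 higher. Col17a1, Itga6 and Itgb4 of the cell adhesion and matrix list are also markers by which basal clusters were named. A lower level of these genes in taste-bud-like than in basal cells is therefore no separate result. All 6 lists lay outside the central range of random lists in these 3 libraries in the main setting. With each library clustered on its own 2 lists lay above and 2 below the range in all 3, and with doublet calls kept or the readout genes kept in clustering 2 lay below. In the ungated cervical library, with 43 such cells, the first 3 lists were above the range at 1.42, 1.33 and 1.87, and the last 3 were within it at 0.09, -0.06 and 0.83. The Hox genes, which mark position along the body axis, had medians of 1.069 and 1.014 in the sorted cervical libraries and 0.97, within the range, in the ungated one, while the tongue had too few measured Hox genes for a median.

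The sorted Krt8-YFP cervical and tongue libraries share sort, genotype and feature list, and compare taste-bud-like cells of the 2 organs, with 704 and 392 cells. Cervical cells had higher levels of Hox genes and higher medians of the detoxification and keratin lists. Tongue cells had higher levels of the developmental regulator Pax1 and the sour-cell channel subunit gene Pkd1l3. Pax1, a transcription factor on chromosome 2 from 147361925 to 147393295, stood at 2.00 CPM (1.09 to 3.35) in cervical and 277 CPM (261 to 293) in tongue cells, 138-fold lower. Pkd1l3, on chromosome 8 from 109614517 to 109674386, stood at 0.856 (0.314 to 1.86) against 103 CPM (93.2 to 112.6). The summed Hox genes stood at 163 CPM (154 to 173) against 18.8 CPM (14.9 to 23.4). Among 3242 genes considered, 88 were at least 2-fold higher in cervical cells and 59 at least 2-fold lower.

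**Figure D2:**
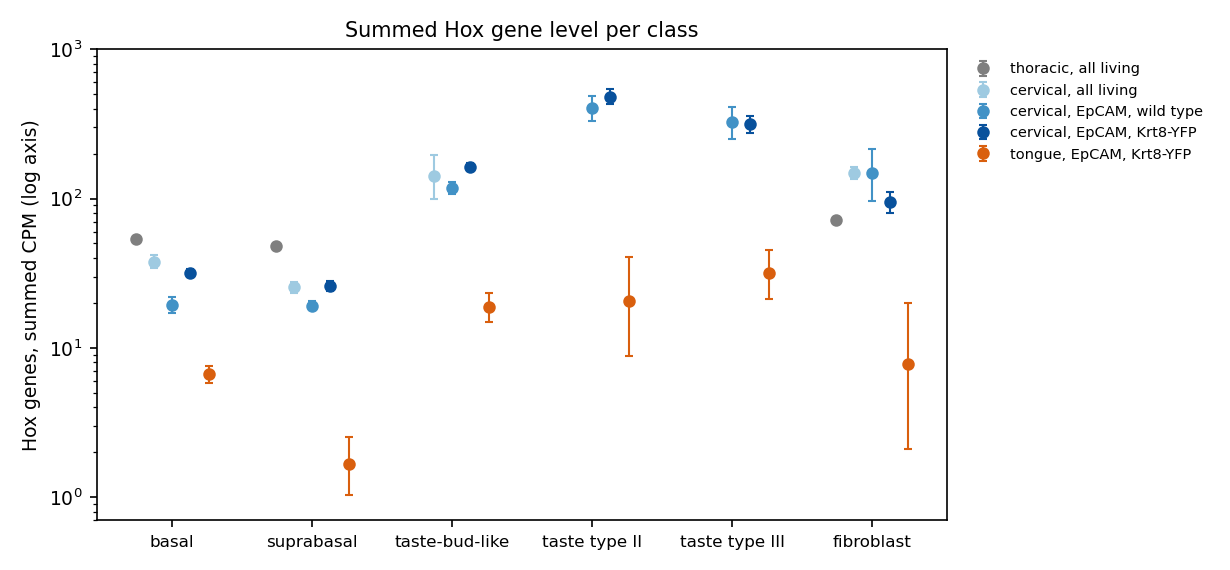
Summed level of the Hox genes (CPM, log axis) per cell class, with exact Poisson 95% intervals that cover counting error only, coloured by library. Taste-bud-like cells stand at 142, 117 and 163 CPM in the cervical libraries and at 18.8 CPM in the tongue library.

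With 10 CPM added to both levels, the highest ratios in cervical taste-bud-like cells among the genes compared belonged to Krt4 (617 against 24.1 CPM, 25.6-fold) and Krt13 (1263 against 119 CPM, 10.6-fold), the paired keratins of non-cornified stratified epithelium. Ifitm1, an interferon-induced membrane protein, stood at 751 against 87.9 CPM, and the water and glycerol channel gene Aqp3 at 245 against 23.2 CPM. Serpinb2 was 9.08-fold, Ly6g6c 8.30-fold, Mal 8.195-fold, Ccdc71l 7.70-fold and the growth factor binding protein gene Igfbp5 6.66-fold higher. Hotairm1, a non-coding RNA of the HoxA locus, stood at 50.2 CPM (45.1 to 55.8) in cervical cells and at 0 in tongue cells, at least 72.2-fold higher. Krt4, Krt13, Aqp3, Serpinb2, Ly6g6c, Mal and Ccdc71l had their highest level in suprabasal cells of the cervical library. Krt4, Krt13, Aqp3 and Serpinb2 were also leading genes of a sub-cluster that carries basal markers, with 95 cervical and 20 tongue cells. Without the sub-clusters with basal markers, Krt4 stood at 55.3 against 16.8 CPM and Krt13 at 123 against 61.4 CPM, so most of their level in the class came from those sub-clusters. On the tongue side, the lipase gene Lipf was at 0 in cervical and 3669 CPM in tongue cells, at least 8570-fold lower in cervical cells, and Dcpp1 was at 0 and 1742 CPM, at least 4069-fold lower. Bpifb1 stood at 0.143 (0.00361 to 0.795) against 1205 CPM, the salivary amylase gene Amy1 at 0.143 (0.00361 to 0.795) against 507 CPM, Dmbt1 at 1.43 against 286 CPM and Sbpl at 0.285 (0.0346 to 1.03) against 240.4 CPM. These 6 genes are products of salivary glands and had their highest level in the gland class of the tongue library, where Lipf stood at 88200 CPM. Basp1, a growth cone protein, was 11.8-fold lower in cervical cells and the protease inhibitor gene Timp3 14.5-fold lower.

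By list, 6 of 8 measured Hox genes were at least 2-fold higher in cervical taste-bud-like cells and 0 lower, with a median log2 ratio of 1.26. Hoxa5, on chromosome 6 from 52201754 to 52204587, stood at 27.5 CPM (23.8 to 31.7) against 0 in the tongue, and Hoxb4 at 22.0 against 0.928 (0.253 to 2.38) CPM. Detoxification and redox genes had a median of 0.84 with 8 of 17 higher and 0 lower, such as Gstm1 at 2.27 and Aldh3a1 at 1.55. Keratins had a median of 0.65 with 3 of 7 higher, epithelial differentiation genes 0.51 with 2 of 10 higher, Notch pathway 0.35, innate defence 0.33 with 4 of 11 higher and 2 lower, BMP and TGFb pathway 0.26, and synapse and transmitter genes 0.23, with Tph1, an enzyme of serotonin synthesis, the only member at least 2-fold higher. Lower in cervical cells were Hedgehog pathway genes at -0.59 with 0 of 4 at least 2-fold lower, stress of dissociation at -0.46, interferon response at -0.43, taste transcription factors at -0.34, Wnt pathway at -0.12, regional transcription factors at -0.12 and genes of fibroblast region and type at -0.70. Among the taste transcription factors, Nkx2-2 was at -1.51 and Etv1 at -1.46, both regulators of sour-sensing cells or neurons. Nkx2-3 was at -2.40 and Tbx3 at -1.92 among regional factors, and Tbx1 at 1.51. Tuft cell genes at 0.10, FGF and EGF pathway at -0.09, cell adhesion and matrix at 0.11 and retinoic acid pathway at 0.23 lay within the random range. With the sorted wild type cervical library in place of the Krt8-YFP one, 228 genes were higher and 142 lower, of which 60 and 46 were among the genes above, and Hox genes had a median of 1.13. In that comparison the median of interferon response turned to 0.69, that of BMP and TGFb pathway to -0.09 that of stress of dissociation to 0.07 and that of regional transcription factors to 0.05, and tuft cell genes were at -0.53. Hedgehog pathway at -0.45, Wnt pathway at -0.20, synapse and transmitter genes at 0.08 and genes of fibroblast region and type at -0.41 were then within the random range, as were the lists that turned other than interferon response. Without the sub-clusters that carry basal markers, 81 were higher and 60 lower, of which 50 and 49 were among the genes above.

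**Figure D3:**
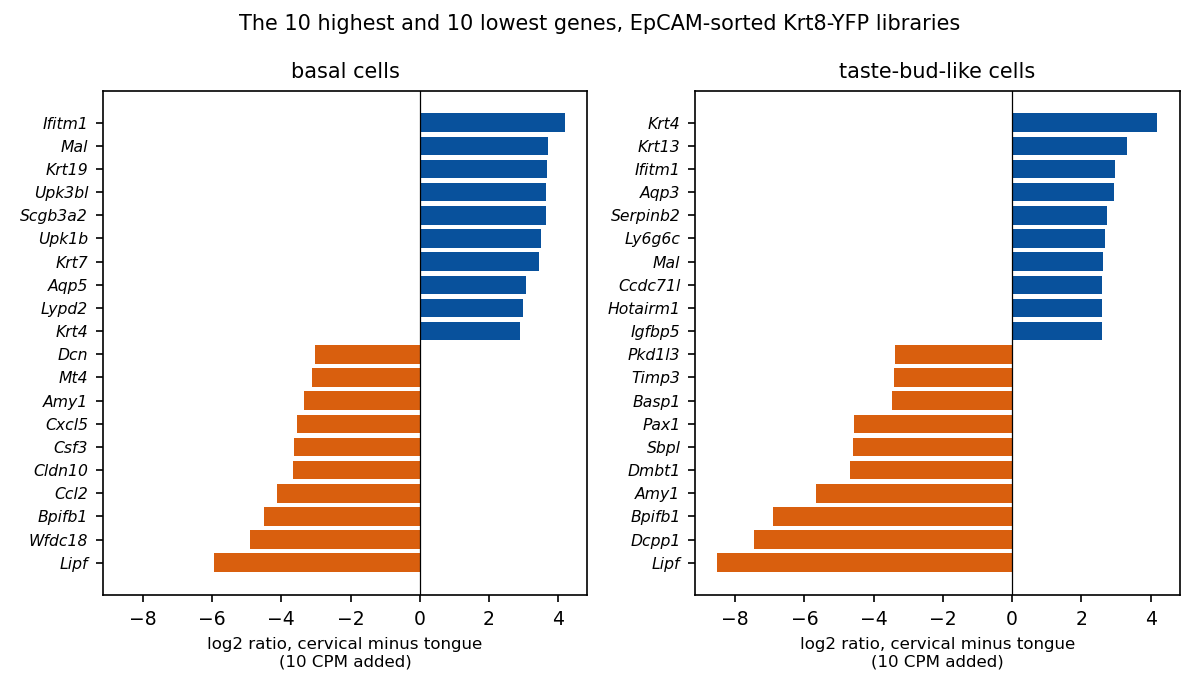
Log2 ratio of CPM, cervical minus tongue with 10 CPM added (horizontal axis), for the 10 highest and 10 lowest genes in basal cells (left) and taste-bud-like cells (right) of the sorted Krt8-YFP libraries. Blue bars are genes higher in cervical cells, such as Krt4 and Ifitm1, and orange bars genes higher in tongue cells, such as Lipf.

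Basal cells of the same 2 libraries, 2422 cervical and 2645 tongue cells, give the difference between these libraries outside the taste class. Cervical basal cells had a higher median of the detoxification list and higher levels of single genes such as Ifitm1, Mal and the uroplakin gene Upk1b. Tongue basal cells had higher levels of single genes such as Ccl2 and Cldn10 and higher medians of the retinoic acid, BMP and TGFb, and FGF and EGF pathway lists. Among 2470 genes, 92 were at least 2-fold higher in cervical cells and 68 lower. Basal cells of the 2 sorted cervical libraries, of 1 segment but unlike genotype and feature list, differed in more genes, 197 and 86 of 2669. With the stricter cell filter those were 64 and 61, against 97 and 64 here. With the looser one they were 86 and 57, against 95 and 86. Which pair differs in more genes thus changes with the cell filter. The sorted cervical libraries also differ in sex of the animals, so their counts are no like background for this comparison. Ifitm1 was 31.2-fold higher at 427 CPM, Mal 36.7-fold, the simple keratins Krt19 and Krt7 20.6-fold and 18.3-fold, Upk1b 110-fold and its relative Upk3bl 19.4-fold. The secretoglobin gene Scgb3a2 stood at 118 CPM (114 to 122) against 0.299 (0.143 to 0.550), the water channel gene Aqp5 at 91.9 against 2.03 CPM, Lypd2 at 70.6 against 0.149 (0.0485 to 0.349) CPM, and Krt4 at 1029 against 129 CPM. Higher in tongue were the chemokine genes Ccl2 (4.50 against 242 CPM) and Cxcl5 (9.59 against 217 CPM), Csf3, a growth factor of granulocytes, at 21.3 against 376 CPM, the tight junction gene Cldn10 at 0.648 against 126 CPM, and Mt4, a metallothionein of stratified epithelium, at 15.03 against 208 CPM. In sorted wild type cervical basal cells Csf3 stood at 371 CPM (361 to 381) and Cxcl5 at 119 CPM, so neither was 2-fold lower than in the tongue in both sorted cervical libraries. Lipf (0 against 609 CPM, at least 6267-fold lower), Wfdc18, Bpifb1 and Amy1 had their highest level in the gland class, as had Cldn10 and Cxcl5, and Dcn, at 36.7 against 369 CPM, and Ccl2 had it in fibroblasts.

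By list, detoxification and redox genes were higher in cervical basal cells with a median log2 ratio of 0.51 and 5 of 15 members at least 2-fold higher, among them Cyp2f2 at 2.65 and Aldh1a1 at 2.07. Innate defence genes had a median of -0.84, with 5 of 10 lower, such as Cxcl1 at -2.83 and Il33 at -2.66, and 2 higher, such as Tslp at 2.10. Retinoic acid pathway genes had a median of -0.74 with Crabp1 at -2.54, interferon response -0.67, BMP and TGFb pathway -0.46 with Inhba at -2.13, FGF and EGF pathway -0.44 with Fgfr1 at -1.76, keratins -0.42, Hedgehog pathway -0.31 with the receptor gene Ptch1 at -1.34, Wnt pathway -0.29 with Lgr5 at -1.68, regional transcription factors -0.27 with Pax1 at -2.80, cell adhesion and matrix -0.18, and genes of fibroblast region and type -1.55. Taste transcription factors at -0.17, Notch pathway at 0.12, epithelial differentiation at 0.17 and stress of dissociation at -0.08 lay within the random range. Clusters 8 and 0 hold 49.0% and 42.2% of the cervical basal cells and clusters 4 and 13 hold 59.1% and 37.2% of the tongue ones. Without cluster 0, 23 genes were higher and 110 lower, of which 14 and 60 were among those above, so most of the genes higher in cervical cells rest on that cluster. With each library clustered alone, the median of innate defence turned to 0.42.

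**Figure D4:**
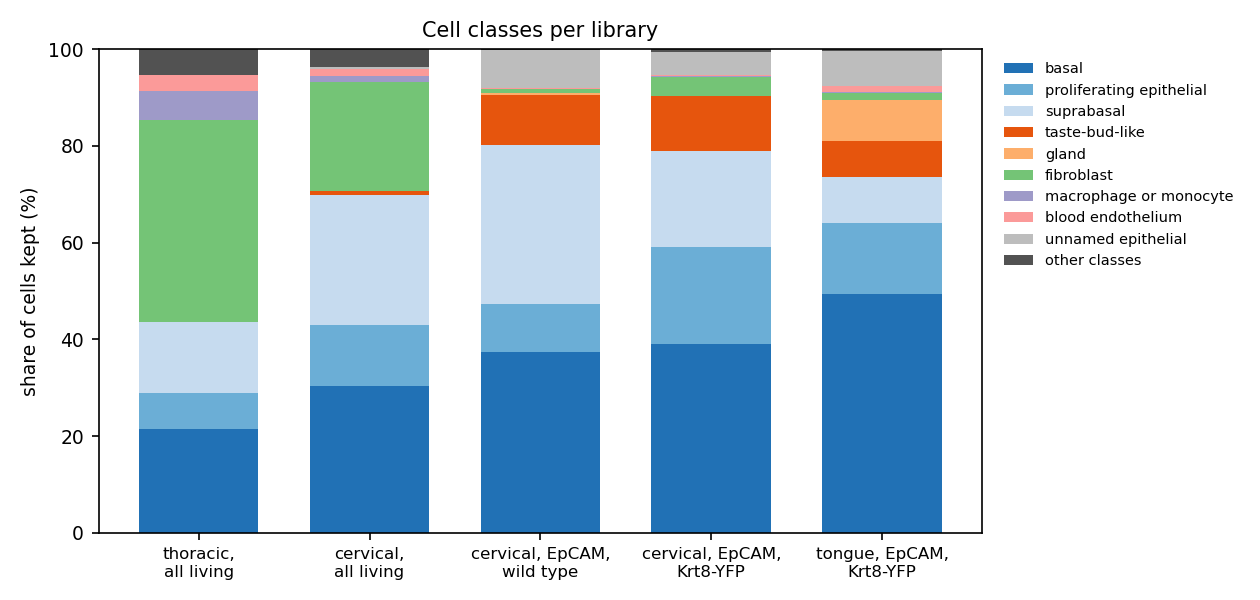
Share of each cell class among the cells kept (percent, vertical axis) in each library, 1 library per group, without error bars. Fibroblasts make up 41.9% of the thoracic and 22.4% of the ungated cervical library and at most 3.77% of the sorted ones; the suprabasal class is drawn but not compared.

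All living cells of the thoracic and cervical oesophagus, both from wild type animals, show which classes differ between segments. The thoracic library held more fibroblasts, macrophages and endothelium, and the cervical library held more epithelial cells. Epithelial cells made up 43.5% (42.5 to 44.5) of thoracic and 71.2% (69.9 to 72.4) of cervical cells, and fibroblasts 41.9% (40.9 to 42.9) and 22.4% (21.3 to 23.6). Macrophages or monocytes made up 5.94% and 1.32%, blood endothelium 3.26% and 1.40%, lymphatic endothelium 1.23% and 0.233%, T or NK cells 1.17% and 0.583%, and Schwann or glial cells 0.689% and 0.156%. Smooth muscle or pericytes made up 0.861% and 1.22%. Mesothelium, the lining of the chest cavity, was found as 56 cells in the thoracic library and 0 of 5144 in the cervical one, which allows a share of up to 0.0583%. The cervical library lost 38.0% of its barcodes to the mitochondrial limit, and its depth was lower, either of which can set these shares.

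Basal cells of the thoracic oesophagus were compared with those of both wild type cervical libraries. Cervical basal cells had higher levels of keratins and of innate defence genes, and thoracic basal cells had higher levels of single genes such as the transcription factors Egr1 and Atf3, the imprinted RNA H19 and the matrix gene Smoc2. Krt6a, a keratin of activated and suprabasal epithelium, stood at 105 CPM (102 to 108) in thoracic, 682 (666 to 699) in ungated cervical and 965 (949 to 982) in sorted wild type cervical cells. The chemokine gene Cxcl2 stood at 37.0, 246 and 1322 CPM. H19 stood at 80.1, 11.3 and 4.55 CPM and Smoc2 at 98.1, 11.6 and 4.98 CPM. Among 2264 genes, 87 were at least 2-fold higher and 21 lower in both cervical libraries.

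Among the genes higher in both, Ifitm1 stood at 1.25 CPM in thoracic and 80.8 and 925 CPM in cervical cells, the claudin gene Cldn7 stood at 1.22, 68.2 and 621 CPM, Mal at 0.366, 59.6 and 315 CPM, and the serine protease gene Tmprss11a at 0.708, 149 and 76.3 CPM. The small heat shock gene Hspb1 was 6.12-fold and 8.21-fold higher, Ccdc71l 6.16-fold and 14.8-fold, and the stress-response gene Ier3 5.21-fold and 9.68-fold. Ftl1-ps1, a ferritin pseudogene whose reads can also come from its parent gene, was 27.9-fold and 23.4-fold higher. Mt4 was 3.20-fold and 63.2-fold lower, Egr1 2.56-fold and 5.48-fold, Fosb 2.53-fold and 2.74-fold and Atf3 2.38-fold and 3.46-fold, and the glutathione transferase gene Gstp1 2.55-fold and 4.22-fold lower. Lars2 and Cavin2 were between 2.75-fold and 3.64-fold lower. Cxcl2 had its highest level in macrophages, Smoc2, Egr1 and Lars2 in fibroblasts, Fosb, Cavin2 and Ier3 in blood endothelium, and Mt4, Gstp1, Mal and Krt6a in suprabasal cells.

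By list, innate defence genes had median log2 ratios of 1.16 in the ungated and 2.32 in the sorted wild type cervical library, with 5 of 7 and 10 of 10 members at least 2-fold higher, such as Tslp at 1.47 and 2.59 and Ccl20 at 1.16 and 2.12. Keratins had medians of 1.09 and 1.36, with Krt17 at 1.35 and 2.57 and Krt23 at 2.28 and 6.04. Epithelial differentiation genes had medians of 0.62 and 0.99, with Dsc2, a desmosomal cadherin, at 2.17 and 3.14. Stress of dissociation genes were lower at -0.31 and -0.71, with 3 and 6 of 16 at least 2-fold lower and 2 higher in each library. Retinoic acid pathway genes had medians of 0.59 and 0.93. The remaining lists lay outside the random range in 1 library at most. Notch pathway had 0.53 and 0.15, FGF and EGF pathway 0.63 and 0.47, interferon response -0.56 and -0.06, detoxification and redox 0.17 and 1.03, and taste transcription factors 0.33 and 1.57, with Runx1 at 1.90 in the sorted library. Hedgehog pathway had -0.75 in the sorted library. BMP and TGFb pathway at 0.29 and 0.20, Wnt pathway at 0.06 and 0.09, regional transcription factors at 0.34 and 0.27, and cell adhesion and matrix at 0.34 and 0.17 were within the range, sex-linked genes had 0.63 and 0.54, though the matrix gene Tnc was at 2.14 and 3.03. The median of all genes considered was shifted by 0.26 and 0.38. Cluster 3 holds 99.4% of thoracic, cluster 7 holds 79.8% of ungated cervical and cluster 0 holds 91.5% of sorted wild type cervical basal cells, and no thoracic cell lies in cluster 0. Cluster 0 scored 1.43 by the taste bud list and 1.42 by the basal list, while the basal list led in clusters 3 and 7. Against the sorted library alone 511 genes were higher and 91 lower, against the ungated library alone 110 and 24, and without cluster 0 60 and 13 in both, while TMM factors gave 57 and 31.

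**Figure D5:**
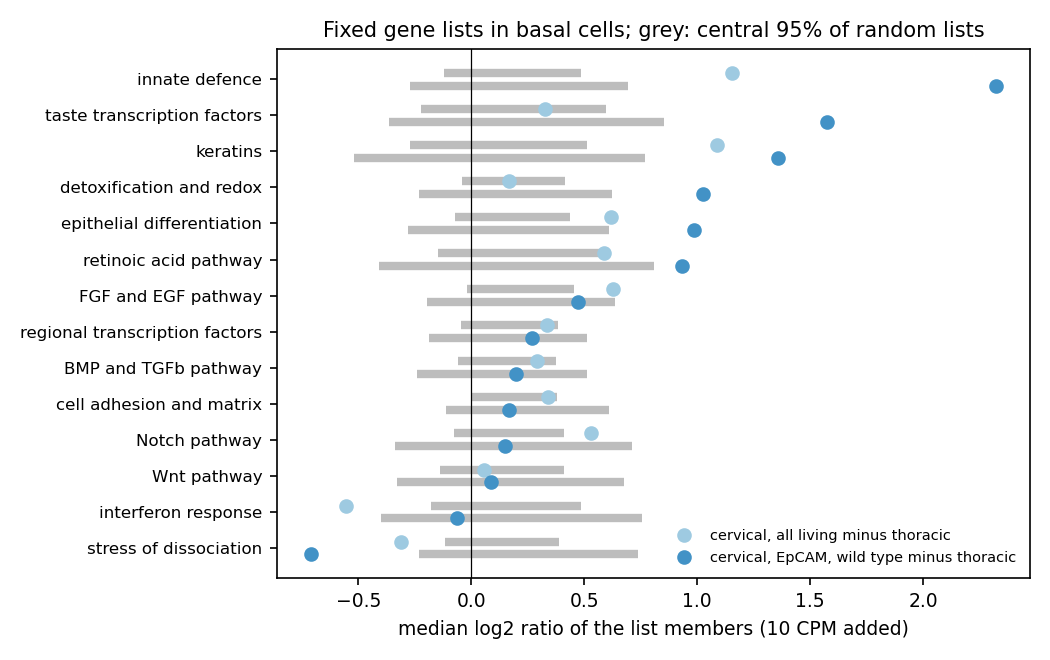
Median log2 ratio of each fixed list in basal cells (horizontal axis, 10 CPM added), cervical minus thoracic, for the ungated (light blue) and the sorted wild type (dark blue) cervical library. Grey bars are the central 95% of random lists; innate defence lies furthest to the right at 1.16 and 2.32.

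Suprabasal cells were compared within clusters 6 and 11, ungated cervical against thoracic, with 502 and 866 cells and with 435 and 403 cells. Keratins and innate defence genes were again higher in cervical cells, with medians of 1.42 and 1.13 in cluster 6 and 1.22 and 0.42 in cluster 11. Retinoic acid pathway genes had medians of 0.59 and 0.70, epithelial differentiation 0.51 and 0.38, and stress of dissociation -0.22 and -0.25. In cluster 11 of the sorted Krt8-YFP cervical against the tongue library, with 113 and 79 cells, stress of dissociation was at 0.68, epithelial differentiation at -0.32, FGF and EGF pathway at -0.17 and interferon response at -0.81.

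Proliferating cells among basal and proliferating epithelial cells, by at least 2 markers after thinning, made up 25.5% (23.8 to 27.3) in the thoracic, 30.1% (28.1 to 32.2) in the ungated cervical, 17.9% (16.1 to 19.7) in the sorted wild type cervical, 26.9% (25.5 to 28.4) in the sorted Krt8-YFP cervical and 19.2% (17.9 to 20.5) in the tongue library. Thinning left out 4, 183, 133, 11 and 18 shallower cells. Without thinning the shares were 51.3%, 42.1%, 27.5%, 41.9% and 33.1%, so the order of the thoracic and the ungated cervical library goes with depth. The share of proliferating cells among basal cells, cervical EpCAM wild type, was 47.6% with the looser and 47.4% with the stricter cell filter, under which 300 and 198 of its cells were named basal, against 1540.

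Fibroblasts of the thoracic and the ungated cervical library, 3649 and 1152 cells, show how these libraries differ outside the epithelium. Cervical fibroblasts had higher levels of the lipid carrier Apoe and the B-cell chemokine Cxcl13. They had higher medians of the keratin, epithelial differentiation, Wnt pathway and FGF and EGF pathway lists. Most members of these pathway lists were not 2-fold higher. Thoracic fibroblasts had higher levels of single matrix genes such as Thbs1 and Hmcn2, though the list of cell adhesion and matrix genes was higher in cervical fibroblasts. Apoe stood at 150 CPM in thoracic and 4683 CPM (4609 to 4757) in cervical fibroblasts, 31.2-fold higher, and Cxcl13 at 1.88 and 277 CPM. Thrombospondin Thbs1 stood at 2738 and 315 CPM, 8.68-fold lower, and hemicentin Hmcn2 at 398 and 26.7 CPM, 14.9-fold lower. Among 2993 genes, 185 were at least 2-fold higher in cervical fibroblasts and 100 lower, and with TMM factors 142 and 146.

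Dpp4, a surface protease of some fibroblast types, was 17.2-fold lower in cervical fibroblasts, Col6a5 14.3-fold, the neuropeptide precursor Tac1 11.4-fold, Fibin 5.84-fold, Col8a1 5.70-fold, Thbs4 5.60-fold and Itih5 4.42-fold. Lars2 was 5.94-fold lower. Among the genes higher in cervical fibroblasts, Krt17 (745 CPM, 37.4-fold), Krt6a (282 CPM, 32.8-fold), Gsto1 (494.5 CPM, 13.97-fold), Aldh3a1 (220 CPM, 16.2-fold) and Gsta4 (475.7 CPM, 10.2-fold) had their highest level in suprabasal cells of these libraries, while Hspb1, 12.3-fold higher, had it in taste-bud-like cells. Dcpp3 stood at 0 in thoracic and 81.8 CPM in cervical fibroblasts, at least 843-fold higher, and Ftl1-ps1 was 16.0-fold higher. By list, Wnt pathway genes had a median log2 ratio of 0.92 with 4 of 12 higher, such as the inhibitors Wif1 at 3.77 and Notum at 1.64, and FGF and EGF pathway genes 0.89 with 6 of 16 higher, such as Fgf10 at 1.17. Retinoic acid pathway genes had 0.67 with Crabp1 at 2.36, cell adhesion and matrix 0.63 with Postn at 1.57, Hox genes 0.61 with Hoxb4 at 1.22, BMP and TGFb pathway 0.49, stress of dissociation 0.47 with Hspa1a at 2.47, interferon response 0.47 with Ifit1 at 3.14, regional transcription factors 0.42 with Tbx3 at 1.99, and innate defence 0.41. Keratins and epithelial differentiation genes both had 1.54, and taste transcription factors 1.06. Sex-linked genes had 1.14 with 3 of 5 higher, the Y-linked Ddx3y, Eif2s3y and Uty, as the sex of the animals differs between these libraries. Genes of fibroblast region and type had 0.18, with Grem1 at 2.62, Wnt5a at 1.99 and Tcf21 at -1.30, and lay within the range with Hedgehog pathway at 0.29, Notch pathway at 0.15, detoxification and redox at 0.28, synapse and transmitter genes at 0.12 and antigen presentation class II at -0.11. Cluster 1 holds 63.7% of thoracic and cluster 5 holds 97.3% of cervical fibroblasts. Over all libraries, cluster 5 had a median of 2564 UMIs and Epcam at 120.6 CPM, against 7080 UMIs and 10.2 CPM in cluster 1. Notum was also a leading gene of taste-bud-like cluster 10. Genes and lists higher in cervical fibroblasts, keratins and epithelial differentiation above all, may therefore hold epithelial RNA, which was not tested.

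The ungated and the sorted wild type cervical libraries compare cells without and with the EpCAM sort. With 1 library each, the sort cannot be told apart from other differences between them. The sorted library held few cells outside the epithelium and a higher share of taste-bud-like cells. Epithelial cells made up 71.2% of the ungated and 99.0% (98.6 to 99.3) of the sorted library, fibroblasts 22.4% and 0.848% (0.592 to 1.18), and macrophages or monocytes 1.32% and 0 of 4126 cells, which allows a share of up to 0.0727%. The 13 clusters without a thoracic cell held 18.6% (17.3 to 19.9) of epithelial cells in the ungated and 95.4% (94.7 to 96.0) in the sorted wild type cervical library, against 55.0% (53.7 to 56.3) in the sorted Krt8-YFP cervical library. The 6 of them with under 5% tongue cells, clusters 0, 9, 12, 14, 21 and 26, a limit chosen after the clusters were seen, held 16.8% (15.6 to 18.1), 82.2% (81.0 to 83.4) and 41.4% (40.2 to 42.7).

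The sorted wild type and the sorted Krt8-YFP cervical libraries share segment and sort and differ in genotype, feature list and sex of the animals. Wild type basal cells had higher levels of innate defence and epithelial differentiation genes. Among 2669 genes, 197 were at least 2-fold higher in wild type cells and 86 lower. Cluster 0 holds 91.5% of the wild type basal cells, and clusters 0 and 8 hold 42.2% and 49.0% of the Krt8-YFP ones. Without cluster 0, 242 were higher and 74 lower, of which 96 and 47 were among those genes. The antigen presentation genes B2m (788 against 87.1 CPM, 9.05-fold) and H2-Q7 (80.1 against 4.34 CPM, 18.5-fold) were higher, as were the antimicrobial lectin gene Reg3g (21.3-fold), Csf3 (17.4-fold), the chemokine gene Cxcl3 (10.5-fold), the interferon-induced genes Slfn2 (10.5-fold) and Ifi203 (5.44-fold), the claudin gene Cldn4 (7.16-fold), the phosphatase gene Ptp4a1 (57.7-fold) and Ftl1-ps1 (21.3-fold). Lower were Nme2 (1.37 against 1136 CPM), Atp6v0c (1.23 against 367 CPM), Rnasek (0.216 against 143 CPM), Timm23 (1.51 against 150 CPM), Mrpl53 (0.0721, interval 0.00183 to 0.402, against 78.4 CPM), B3gnt2 (1.37 against 89.3 CPM), Ube2v1 (0.938 against 71.0 CPM), BC004004 (10.0 against 340 CPM), Tomm6 (7.14 against 178 CPM) and Grcc10 (9.60 against 150.5 CPM). All of these except Grcc10 were at least 10-fold lower in basal cells of each library with the older feature list than of each with the newer one. B2m, H2-Q7, Ptp4a1 and Ftl1-ps1 had their highest level in fibroblasts and Reg3g in taste-bud-like cells.

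By list, innate defence genes had a median of 1.21 with 6 of 10 higher in wild type basal cells, epithelial differentiation genes 1.00 with 7 of 14 higher, interferon response 0.74, against a shift of 0.13 in the median of all genes, stress of dissociation -0.30 and cell adhesion and matrix -0.32. Stress of dissociation turned to 0.79 with the looser and 0.67 with the stricter cell filter. In taste-bud-like cells, 428 wild type and 704 Krt8-YFP, interferon response genes had a median of 1.32 with 6 of 10 higher, among them Isg15 at 3.31 and Cxcl10 at 2.73, epithelial differentiation genes 0.85, innate defence 0.39, keratins 0.36, which turned to -0.84 with each library clustered on its own, stress of dissociation 0.32 with Hspa1a at 3.16, retinoic acid pathway 0.30, Hox genes -0.48 with 0 of 8 beyond 2-fold, BMP and TGFb pathway -0.45 and taste transcription factors -0.28. Krt8 itself, on chromosome 15 from 101996698 to 102004482, stood at 52.2 CPM (45.2 to 60.0) in wild type and 756 CPM (736 to 777) in Krt8-YFP taste-bud-like cells, while Krt18, its partner keratin, stood at 2800 and 2762 CPM. Krt8 was low in all libraries with the older feature list, at 0.557 CPM over the epithelial classes of the ungated cervical and 0 in the thoracic library. With the looser and the stricter cell filter, 86 and 64 genes were higher in wild type basal cells, of which 39 and 32 were among the 197, and 300 and 198 wild type cells were named basal.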

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

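The counts of the reporter feature were examined only after the libraries were seen, and no explanation of them was tested. YFP, the fluorescent reporter of the Krt8-YFP mice, is a feature that the comparisons of the report do not use. It had 105 UMIs in the sorted Krt8-YFP cervical library and 314 in the tongue library, against 2 in the thoracic library, which comes from wild type mice and lists the same feature. As CPM over all UMIs of the library this is 1.08 (0.884 to 1.31), 3.71 (3.31 to 4.15) and 0.0123 (0.00149 to 0.0444). Both wild type cervical libraries do not list YFP.

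By class, YFP was seen in 7.53% (5.69 to 9.73) of the taste-bud-like cells of the sorted Krt8-YFP cervical library and 7.65% (5.22 to 10.7) of those of the tongue library, and in 0.330% and 0.454% of their basal cells. Median depths were 8126.5 and 10629.5 UMIs in taste-bud-like cells and 12202.5 and 12126 in basal cells, so depth does not favour the taste-bud-like cells. Gland cells of the tongue library carried it most often, in 147 of 460 cells or 32.0% (27.7 to 36.4), with 244 of the 314 UMIs. In the cervical library 16 of the 242 cells of the unnamed epithelial cluster 21, or 6.61% (3.83 to 10.5), carried it. A count of 0 in a cell does not show that it lacks the reporter, since few UMIs were seen.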

How the results depend on the processing

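The alternatives that remove the highest doublet scores, leave out mixed sub-clusters, cluster 0, gland genes or either wild type cervical library, or replace the Krt8-YFP cervical library were chosen after the results were seen. Of 521 settings of the 47 values that answer the comparisons, 422 stayed within their interval or within 1.5 times the main count and 99 moved. These are shares and counts, which have no sign to reverse. Of 3271 settings of the 376 other values, 2186 stayed, 1081 moved and 4 reversed. The thoracic share of taste-bud-like cells lay between 0 and 0.0265% and the ungated cervical one between 0.936% and 1.25% in the settings of cell filter, doublets, clustering and thinned markers. By markers without thinning they were 5.01% and 5.46%, with overlapping intervals. By thinned markers their intervals were apart, though neither exceeded the share in fibroblasts, which are not a clean background. Of the lists outside the range in taste-bud-like against basal cells of all 3 sorted libraries, between 2 and 3 lay above it and between 2 and 5 below it. More genes were higher than lower in cervical than thoracic basal cells in every setting run. In cervical against tongue basal cells, with 92 higher and 68 lower, more genes were lower than higher by a mean over cells (92 and 98), with no CPM minimum (135 and 142) and without cluster 0. With TMM factors fibroblasts had 142 higher and 146 lower genes, against 185 and 100. Depth limits the ungated cervical library most, and thinning left out 183 of its cells for proliferation. The cause was not tested for the values below, except that fewer or more genes can pass where the CPM minimum, the required libraries or the cells of a class differ by construction.

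Main values in percent are, in the order thoracic, ungated cervical, sorted wild type cervical, sorted Krt8-YFP cervical and tongue, 0, 1.17, 10.5, 11.9 and 7.55 for the share of taste-bud-like cells and 25.5, 30.1, 17.9, 26.9 and 19.2 for that of proliferating cells. With at least 1000 genes, at least 2500 UMIs and at most 10% mitochondrial UMIs, the sorted wild type cervical library had 9.18% taste-bud-like and 47.4% proliferating cells, and the ungated cervical library 33.2% proliferating, 81.6% epithelial (main 71.2%) and 16.4% fibroblast (22.4%). Cervical against thoracic basal cells had 56 higher (87) and 10 lower genes (21), wild type against Krt8-YFP cervical basal cells had 64 higher (197), and their stress of dissociation reversed from -0.30 to 0.67. With at least 200 genes, at least 500 UMIs and at most 25% mitochondrial UMIs, proliferating shares were 33.5% in the ungated and 47.6% in the sorted wild type cervical library, epithelial shares 45.7% in the thoracic (43.5%), 74.9% in the ungated and 96.3% in the sorted wild type cervical library (99.0%), and fibroblasts 39.3% in the thoracic (41.9%) and 15.4% in the ungated cervical library. Cervical against thoracic basal cells had 11 lower genes, wild type against Krt8-YFP cervical basal cells 86 higher and 57 lower (86), with 10 lists outside the random range (5) and stress of dissociation reversed to 0.79.

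With doublet calls kept, taste-bud-like shares were 8.30%, 10.852% and 6.10% in the sorted wild type cervical, sorted Krt8-YFP cervical and tongue libraries, type II-like shares 15.3% (10.0%), 12.6% (10.1%) and 14.5% (8.16%), and the type III-like share of the tongue 23.3% (18.9%). Proliferating shares were 21.5%, 27.8% and 16.1% in the thoracic, ungated and sorted wild type cervical libraries, epithelial cells 45.0% of the thoracic, and fibroblasts 39.9% of the thoracic and 23.75% of the ungated cervical library. With each library clustered on its own, taste-bud-like shares were 6.86% and 10.953% in the sorted wild type and Krt8-YFP cervical libraries, type II-like 16.3% and type III-like 13.1% (8.41%) in the sorted wild type one, and proliferating shares 22.7%, 30.5% and 26.4% in the thoracic, sorted wild type cervical and tongue libraries. Epithelial cells were 74.7% of the ungated and 100% of the sorted wild type cervical library, with 0 fibroblasts (0.848%) in the latter. Innate defence in cervical against tongue basal cells reversed from -0.84 to 0.42, and keratins in wild type against Krt8-YFP cervical taste-bud-like cells from 0.36 to -0.84.

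With the highest doublet scores removed, taste-bud-like shares were 9.5275% and 10.7% in the sorted wild type and Krt8-YFP cervical libraries and the proliferating share 20.041% in the former. By at least 3 taste markers after thinning, taste-bud-like shares were 9.5287% in the sorted wild type cervical and 10.51% in the tongue library. Without the sub-clusters with basal markers they were 9.01% in the sorted wild type and 10.054% in the sorted Krt8-YFP cervical library, with 17.4% type III-like (14.3%) in the latter. At resolution 2 the proliferating share was 22.002% in the thoracic and 21.7% in the sorted wild type cervical library, and with another seed 22.002% in the thoracic. At resolution 0.5 it was 15.4%, 25.2% and 17.2% in the sorted wild type cervical, sorted Krt8-YFP cervical and tongue libraries, fibroblasts were 23.7% of the ungated cervical library, and 5 lists lay below the range in taste-bud-like against basal cells (3). Without thinning the proliferating shares of the 5 libraries were 51.3%, 42.1%, 27.5%, 41.9% and 33.1%, by at least 1 marker 38.986%, 47.7%, 29.972%, 38.6% and 29.6%, and by at least 3 markers 19.5%, 21.7%, 11.5%, 20.2% and 13.5%.

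For counts of genes, TMM factors gave 57 higher in cervical against thoracic basal cells, and a mean over cells gave 133, with 5 lists below the range in taste-bud-like against basal cells. With no CPM minimum there were 163 higher there, 409 higher in fibroblasts (185), 142 lower in cervical against tongue basal cells (68), 181 higher and 118 lower in taste-bud-like cells (88 and 59), and 138 lower in wild type against Krt8-YFP cervical basal cells (86). Without mitochondrial and ribosomal protein genes in the total, lower genes numbered 43 in cervical against thoracic basal cells, 111 in cervical against tongue basal cells and 162 in wild type against Krt8-YFP cervical basal cells. Without cluster 0, 13 were lower in cervical against thoracic basal cells, and 23 higher (92) and 110 lower in cervical against tongue basal cells. Without the ungated cervical library, 511 were higher and 91 lower in cervical against thoracic basal cells. With the sorted wild type cervical library in place of the Krt8-YFP one, 228 were higher and 142 lower in taste-bud-like cells.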

Other observations

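The explanations of the Krt8 level, the EpCAM gate with the choice of 6 clusters, and the explanations of the Hox level by free RNA and by depth were tested only after those results were seen. Among the taste-bud-like cells, a sub-cluster of 181 cells was led by Shh, the Hedgehog ligand that marks precursor cells of taste buds, at 208 CPM. It held 5 cells of the ungated cervical, 48 of the sorted wild type cervical, 49 of the sorted Krt8-YFP cervical and 79 of the tongue library, and its leading genes included Ptch1, a Hedgehog receptor and target, the BMP and activin inhibitor Fst, and Lipf and Bpifb1, which had their highest level in the gland class of the tongue library. Entpd2, an ectonucleotidase of type I taste cells, stood at 211, 149.7, 192 and 243 CPM in taste-bud-like cells of the 4 libraries. Another sub-cluster of 34 cells was led by Mki67, Top2a and other genes of dividing cells, with a median of 24626 UMIs and 27 of its cells in the sorted Krt8-YFP cervical library. Sub-clusters led by other genes were mostly of 1 library. Of 226 cells of one, 190 came from the sorted wild type cervical library, and of 169 cells of another led by Ecm1 and Mme, 168 came from the tongue.

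Epithelial clusters left unnamed differed between organs. Cluster 21, led by Bpifa1, the antimicrobial lectin gene Reg3g, the surfactant protein gene Sftpd and Scgb3a2, made up 4.68% of epithelial cells in the sorted wild type cervical and 4.09% in the sorted Krt8-YFP cervical library. Cluster 26, led by Clca3b, Psca, Duoxa2 and the interferon-induced gene Isg15, made up 3.28% and 1.02%. Cluster 23, led by the contractile genes Tagln, Acta2, Cnn1 and Myh11 with Epcam at 1729.5 CPM, made up 7.52% of epithelial cells of the tongue library. Parathyroid hormone Pth had 14476 UMIs over all deposited barcodes of the sorted wild type cervical library, 12 in the ungated cervical and 0 in the other libraries. Among the cells kept it was seen in 275 and 8 cells of these 2 libraries.

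Krt8 was lower in wild type than in Krt8-YFP cervical taste-bud-like cells, with a log2 ratio of -3.62. Less mature cells stay open, since the test covers only 43 wild type and 71 Krt8-YFP type II-like cells, named by their type II genes, and its values go both ways. There the taste receptor total in the wild type library was 1.27 times that in the Krt8-YFP library (at least 0.986 by the limits of both), but Gnat3 was 0.497, Plcb2 0.692, Trpm5 0.761 and Tas1r3 0.548 times, with Krt8 at 0.121 times (at most 0.168), and taste transcription factors had a median log2 ratio of -0.28 in the whole class. For the gene annotation, Krt8 over the epithelial classes stood at 0, 0.557 and 8.66 CPM in the 3 libraries with the older feature list, at most 0.0786 times the 110.2 CPM of the sorted Krt8-YFP cervical library, and 10 genes showed a like step in basal cells against 2 in the reverse direction. Genotype and annotation cannot be told apart, because each older list goes with wild type mice and each newer one with Krt8-YFP mice.

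Clusters 0, 9, 12, 14, 21 and 26, the 6 without a thoracic cell and with under 5% tongue cells, held 82.2% of epithelial cells in the sorted wild type cervical library, 41.4% in the sorted Krt8-YFP cervical and 16.8% in the ungated cervical library. The 2 sorted libraries lay 40.8 points apart, or 40.4 over all 13 clusters without a thoracic cell. This cannot decide on the EpCAM gate as the cause. The 2 sorted libraries also differ in genotype, feature list and sex of the animals, and clustering was without integration. Epcam stood at 1260, 1769, 1041, 1319, 1600 and 740 CPM in these 6 clusters, in the order above. It stood at 328, 343, 540 and 208 CPM in clusters 3, 6, 7 and 11. Those hold most thoracic basal and suprabasal cells and most ungated cervical basal cells. Airway or thyroid tissue in the dissection may be a source and cannot be told apart from oesophageal epithelium by the fixed markers. The parathyroid gene Pth was seen in 275 kept cells of the sorted wild type cervical library and in 0 of the sorted Krt8-YFP one. Its highest level in these 6 clusters was 14.85 CPM, in cluster 9. In 5 of these 6 clusters under 3 airway and under 3 thyroid or parathyroid markers were seen in 5% of cells, but the bound set beforehand was too strict, since the fixed list holds markers of ciliated and secretory airway cells and none of airway basal cells, and Scgb3a2 stood at 257.6 CPM (249.2 to 266.2) in cluster 0 and 6.93 CPM (5.64 to 8.43) in cluster 8 of the sorted Krt8-YFP cervical library. Cluster 21 held 3 airway markers, Scgb1a1 at 207 CPM, Scgb3a2 at 555 CPM and Tppp3 at 490 CPM, so comparisons that rest on cluster 0 carry this doubt.

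Hox genes stood higher in cervical than in tongue taste-bud-like cells. Free RNA is argued against by a Hox level 5.13 times that of the higher of basal and suprabasal cells, in the lower of the 2 sorted cervical libraries. Doublets with fibroblasts are argued against by a Hox level 849.8 times what the fibroblast share that Col1a2, Col3a1 and Dcn allow, 0.0935% and 0.165%, would bring. Depth and annotation are argued against by the tongue library, which has the same feature list as the sorted Krt8-YFP cervical library, since 701.6 Hox UMIs were expected at the cervical level and the upper limit of the 81 seen is 100.7, or 14.35%. The difference is not limited to taste-bud-like cells, since in the same 2 libraries the Hox level was 31.7 against 6.64 CPM in basal cells, 47.3 against 6.66 in proliferating cells and 94.4 against 7.74 (2.11 to 19.8) in fibroblasts, and a difference between the organs stays an untested hypothesis from 1 library each.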
